A study of Thermothelomyces thermophilus with 4 samples.

How the data were processed

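Poly(A) RNA was sequenced from shaken cultures of the thermophilic filamentous fungus Myceliophthora thermophila (Thermothelomyces thermophilus), which breaks down plant cell walls, grown at 45 °C with 1 of 4 crop straws as the carbon source. Each of oat, triticale, canola and flax straw was represented by 1 library, so the data set holds 4 libraries and no replicate culture. Per the labels, the oat, triticale and flax cultures were taken after 24 h and the canola culture after 30 h, so that straw and culture time cannot be told apart for canola. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with an Illumina mRNA-Seq kit. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here.

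The authors deposited 1 table of FPKM values (read counts divided by gene length and library total), with 9110 numbered gene models and the length of each. Per the file headers, the other numeric column is the gene length in bases. The product of FPKM and length, divided by 1000, summed to 1000000 in each column, so the authors scaled to the reads assigned to the listed genes. Every such product was a whole multiple of the smallest one in its column, with 100% of values within 0.001 of a whole read. Reads per gene and library totals were therefore recovered from the FPKM values and lengths. The totals were 7308467 reads for oat, 6495371 for triticale, 7977329 for canola and 7955444 for flax. For a gene of the median length, 1733 bases, the limit that a count of 0 allows (3 reads) corresponded to 0.237, 0.267, 0.217 and 0.218 FPKM, in the same order. Exact Poisson intervals (95%) of single values and exact Clopper-Pearson intervals (95%) of ratios between 2 libraries were computed from the recovered reads. They cover counting error only, and PCR copies without molecular identifiers are not independent molecules.

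The numbers in the table were matched to a RefSeq gene table (assembly ASM22609v1 of strain ATCC 42464) as the number in the locus tag. Of the 9110 models, 9087 matched, and 9075 of these had the same length as the RefSeq gene span, introns included. FPKM per gene span understates genes with long introns, in every library alike. The RefSeq table gave a gene symbol for 6 models and a locus tag for the rest, and no product descriptions. The 29 gene lists (enzyme families, transporters, central metabolism, stress, spore and translation genes) that had been fixed by patterns in product text matched 0 genes, so none of them could be evaluated. Since no build is named for the deposited values, no genomic positions are given. The RefSeq table was used only for names, for the check of lengths, for which genes lie next to each other and for whether neighbouring spans overlap. The kit is not described as stranded in the sources used here, so reads of overlapping or antisense genes may not be separated.

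The analysis used the 8230 models with a mean FPKM of at least 1 over the 4 libraries and left out 880. Values were compared as log2(FPKM + 1), a scale that understates changes of low genes. Fold rules and gaps between classes use this scale, while ratios between 2 straws given for single genes are ratios of FPKM. Cereal straws (oat and triticale, both grasses) were compared with dicot straws (canola and flax). This grouping follows from the plants and is not in the labels. A gene counted as higher in a class when its lower library in that class was at least 2-fold above the higher library of the other class. The same rule was applied to the other 2 ways of splitting the 4 libraries into pairs. Oat was compared with triticale, canola with flax, and each straw with the other 3 at a ratio of 2-fold or more. These comparisons have no replicate check and no p-value. For the class comparison, limma 3.58.1 in R 4.3.3 was also fitted to the log2 values (moderated test with a mean-variance trend, two-sided, Benjamini-Hochberg adjusted p under 0.05), with the straw as the unit. Its p-values measure the spread between the 2 straws of a class, with 2 residual degrees of freedom, and not the spread between replicate cultures. The moderation also borrows variance across genes, so the p-values rest on more than the spread of the gene itself.

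The fit and the fold rule were tested on simulated data for the cereal against dicot comparison (8230 genes, 200 changed, coefficient of variation 0.2 between libraries). The fold rule recovered 16% of the 50 genes changed 2-fold, 92% of those changed 4-fold and 100% of those changed 8-fold or 16-fold. The corresponding shares for limma were 42%, 98%, 100% and 100%. Of 8030 unchanged genes, 2 passed the fold rule and 7 passed limma. The simulated libraries of a class had the same mean for every gene and no trend with gene length or expression level. In the data 1198 genes were at least 2-fold apart between oat and triticale and 937 between canola and flax. The simulated counts are therefore not the false-call rate of the class sets.

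Genes were named by a rule. For the class comparison these were the 10 genes per direction with the widest gap between classes and an FPKM of at least 10 in both libraries of the higher class. For the other comparisons they were the 5 per direction with the widest ratio and at least 10 FPKM in the higher library or libraries. Among genes without a name beyond the locus tag, only the top 2 per direction were taken. The 10 most abundant models were also named. All 6 genes with a symbol are given as well, because no other genes could be tied to a function; that addition was made after the table was seen. The design, the named-gene rule and most alternatives were fixed before the data were examined. The alternatives were pseudocounts of 0.1 and 10, no filter, a filter at a mean FPKM of 10, median centring, upper-quartile scaling, a 4-fold rule, leaving out libraries, and limma without the trend. Removal of each library's trend with gene length, with mean level, or with both in 3 alternating rounds (lowess, span 0.3, statsmodels 0.14.6) and limma-voom on the recovered reads were added after seeing the data. All calculations other than limma used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.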

Results

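RNA from mycelium grown on 4 straws was measured to compare the transcript response of the fungus to different plant biomass. The libraries held 6495371 (triticale) to 7977329 (canola) reads assigned to genes. Between 272 (flax) and 309 (triticale) of the 9110 gene models had 0 reads. Median FPKM over all models was 18.1 on oat, 13.3 on triticale, 19.1 on canola and 18.6 on flax straw. The libraries were similar across genes: Spearman's rho of log2(FPKM + 1) was 0.955 for oat and triticale and 0.922 for canola and flax. It was 0.932 for oat and canola and 0.923 for oat and flax, so these pairs were as alike as the 2 dicot straws. It was 0.880 for triticale and flax and lowest, 0.868, for triticale and canola. These coefficients are across genes, which are not independent replicates.

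The 10 models with the highest mean FPKM were at 3257 FPKM or more on every straw. They included 4 short models, MYCTH_2071285, MYCTH_2071504, MYCTH_2071514 and MYCTH_2071953, which are 188 to 497 bases long and lie next to each other in RefSeq gene order. Together they took 1.96% of reads on oat, 1.87% on triticale, 2.15% on canola and 3.17% on flax, and each was 1.42 to 1.72 times as high on flax as on canola. The model numbered 2071561, which matched no locus tag, had a similar profile, with 15400 FPKM on oat, 13798 on triticale, 16541 on canola and 24062 on flax. Flax also gave the highest values of MYCTH_2314451 (8711 FPKM, against 3871 to 4925 on the other straws), model 2121175 (8411 against 4166 to 4948), MYCTH_2141513 (5703 against 3617 to 4754) and MYCTH_2297659 (5599 against 3257 to 4208). MYCTH_2307942, a model of 301 bases, went the other way, with 11841 FPKM on triticale, 7739 on canola, 6909 on oat and 3259 on flax. The 10 most abundant models of each library took 15.2% of summed FPKM on oat, 14.8% on triticale, 16.8% on canola and 23.3% on flax. Summed FPKM gives short models more weight. The 10 models with the most reads took 6.41% of reads on oat, 6.36% on triticale, 6.31% on canola and 9.40% on flax.

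The first comparison asked which genes set growth on the cereal straws (oat and triticale) apart from growth on the dicot straws (canola and flax). On both cereal straws 90 genes were at least 2-fold above both dicot straws, and on both dicot straws 150 genes were at least 2-fold above both cereal straws. The 90 cereal-higher genes took 5.41% of reads on oat and 5.11% on triticale, against 1.07% on canola and 0.858% on flax. The 150 dicot-higher genes took 2.09% of reads on canola and 2.16% on flax, against 0.552% on oat and 0.342% on triticale. Fold rules, gaps and ratios between classes are on the scale of FPKM + 1, while ratios between 2 straws are of FPKM. Genes described as widest are ranked on the scale of FPKM + 1 among genes with at least 10 FPKM in the higher library or libraries. The median ratio between the class means was 4.52-fold for the cereal-higher genes and 3.81-fold for the dicot-higher genes. The 2 sets were chosen on these same libraries, so their shares describe the sets and are not a test. When 1 library was left out, the other straw of its class stood for the class alone. The 2 counts were then 118 and 1356 without oat, 143 and 166 without triticale, 279 and 369 without canola, and 132 and 519 without flax. Under this rule leaving out a library can only keep or add genes, so these counts could not fall and do not test the sets. By construction the 1356 held all 828 genes that were at least 2-fold lower on triticale than on every other straw. With all 4 libraries and a pseudocount of 10 the 2 counts were 58 and 34. They were 101 and 141 after median centring and 99 and 126 after upper-quartile scaling. With each library's trend with gene length removed they were 103 and 116, and with the trend with expression level removed 111 and 119. With both trends removed they were 108 and 110, so the larger number on the dicot side depends on the processing.

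The widest gap on the cereal side was that of MYCTH_39279, with 1210 FPKM on oat (95% counting interval 1185 to 1235) and 596 on triticale (577 to 615), against 1.61 on canola (0.858 to 2.76) and 2.49 on flax (1.52 to 3.84). MYCTH_49824 followed, with 2720 FPKM on oat and 3656 on triticale against 74.1 on canola and 23.4 on flax. On the dicot side MYCTH_112322 had 233 FPKM on canola and 255 on flax, against 29.2 on oat and 17.8 on triticale. MYCTH_109542 had 369 FPKM on canola and 163 on flax, against 18.3 on oat and 32.3 on triticale. All 4 passed the limma test across straws. The log2 ratio of cereal to dicot was 8.14 ± 0.39 (SE, adjusted p = 9.9e-05, limma) for MYCTH_39279 and 6.20 ± 0.48 (adjusted p = 0.00187, limma) for MYCTH_49824. It was -3.36 ± 0.31 (adjusted p = 0.00388, limma) for MYCTH_112322 and -3.28 ± 0.43 (adjusted p = 0.0141, limma) for MYCTH_109542. With a pseudocount of 10 the ratios of MYCTH_39279 and MYCTH_49824 were 6.16 and 5.90. That of MYCTH_49824 was 7.01 without canola and 5.39 without flax. Without the mean-variance trend MYCTH_109542 did not pass (adjusted p = 0.0836, limma). With no filter on low values none of the 4 passed (adjusted p = 0.251 to 0.435, limma). In the order given above, the ratios were 7.63, 6.42, -3.71 and -2.89 without oat. Without triticale they were 8.65, 5.99, -3.02 and -3.68. A fit with 1 straw left in a class has no spread within that class, so no p-value is given for it. At the 4-fold level 30 genes were cereal-higher and 9 dicot-higher, and the largest gap between classes was 171-fold on the cereal side and 7.76-fold on the dicot side, both of FPKM + 1.

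Only 6 of the gene models carried a symbol, and they cover different substrates. The transcript of cbdA, which encodes cellobiose dehydrogenase, an oxidative enzyme of cellulose breakdown, was higher on both cereal straws: 807 FPKM on oat and 498 on triticale, against 267 on canola and 119 on flax. Its gap between classes was 1.86-fold and therefore outside the 2-fold sets. The transcripts of cat1, a catalase that removes hydrogen peroxide, and phy1, a phytase that releases phosphate from phytate, were higher on both dicot straws. The cat1 values were 25.6 FPKM on canola and 135 on flax, against 14.1 on oat and 4.32 on triticale, a gap of 1.76-fold and also outside the 2-fold sets. The phy1 values were 8.76 FPKM on canola and 11.9 on flax, against 3.72 on oat and 1.30 on triticale, a gap of 2.07-fold on the scale of FPKM + 1. The log2 ratio of cereal to dicot was 1.82 ± 0.41 (SE) for cbdA, -2.75 ± 0.76 for cat1 and -1.77 ± 0.50 for phy1. Without flax the cat1 ratio was -1.57, without triticale -1.99, without oat -3.50 and without canola -3.93. None passed the limma test over all 8230 genes (adjusted p = 0.12, 0.194 and 0.207 in that order). Adjusted over the list alone, the 5 tested genes with a symbol, all 3 passed (limma adjusted p = 0.00964, 0.0119 and 0.0119). That list was set after the table was seen. Over all genes, cbdA passed under median centring (adjusted p = 0.0152, limma) and upper-quartile scaling (0.0342), while cat1 passed under median centring (0.0208) and not under upper-quartile scaling (0.101). Over the alternatives with all 4 libraries the limma adjusted p ranged from 0.00475 to 0.52 for cbdA and from 0.0119 to 0.521 for cat1. It ranged from 0.0506 to 0.52 for phy1, which the filter at a mean FPKM of 10 leaves out. With 1 library left out the ratio was 1.24 to 2.40 for cbdA and -2.29 to -1.25 for phy1.

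Of the other 3 genes with a symbol, ganA and gla1 did not pass the limma test between the classes with all 4 libraries, and lcc1 was below the filter and not tested. The ganA transcript, which encodes an endo-galactanase acting on pectic galactan, was highest on canola, at 275 FPKM (265 to 286), with 142 on oat, 131 on triticale and 91.5 on flax. The gla1 transcript, which encodes glucoamylase, a starch-degrading enzyme, was also highest on canola, at 83.7 FPKM (79.6 to 87.8), with 36.9 on oat, 22.7 on flax and 20.3 on triticale. The canola culture was also the one grown for 30 h. The log2 ratio of cereal to dicot was -0.22 ± 0.46 (SE, adjusted p = 0.864, limma) for ganA and -0.66 ± 0.57 (adjusted p = 0.65, limma) for gla1. Without the canola library the sign of both ratios turned, to 0.57 for ganA and 0.26 for gla1. With the flax library left out, canola alone stood for the dicot straws, and the ratios were -1.01 for ganA and -1.57 for gla1. The laccase gene lcc1 was close to the detection limit, with 2 reads on oat, 1 on triticale, 4 on canola and 2 on flax, so no difference was detectable at this depth.

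**Figure D1:**
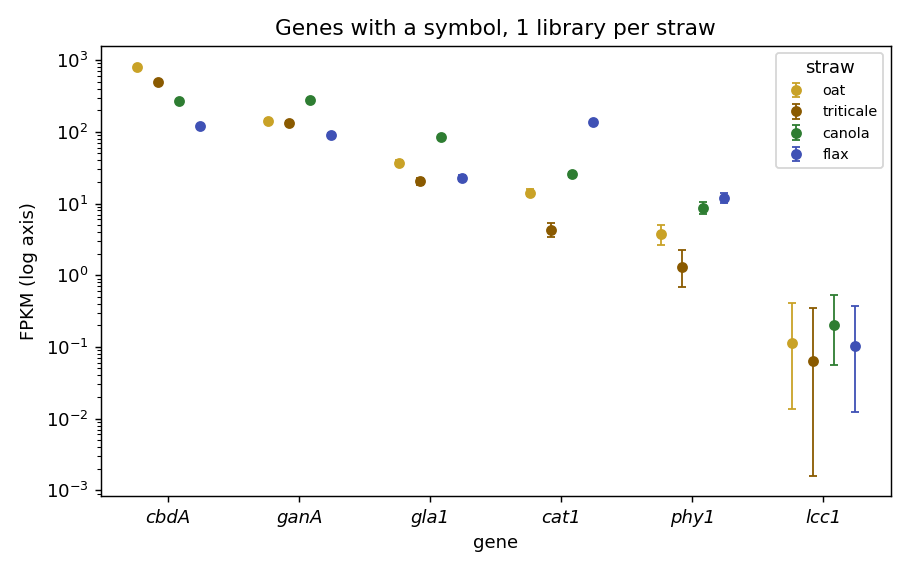
FPKM (vertical log axis) of the 6 genes with a symbol (horizontal axis) on each straw, 1 library per straw, with exact Poisson 95% intervals that cover counting error only. The cbdA points of oat (807) and triticale (498) lie above those of canola (267) and flax (119), and the cat1 and phy1 points lie in the reverse order by class.

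With the straw as the unit, limma called 55 genes, 45 of them higher on cereal and 10 higher on dicot straws, all of which were also in the 2-fold sets. At an unadjusted p under 0.05 there were 313 and 786 genes. After median centring, which subtracted -0.14 on the log2 scale from triticale and 0.05 to 0.08 from the other libraries and so raised triticale against them, the calls were 87 and 135, and after upper-quartile scaling 70 and 50, so the share in each direction depends on the scaling. Limma without the mean-variance trend called 16 and 1, and with no filter on low values 0 and 0, with 348 and 501 genes at an unadjusted p under 0.05. With 1 library left out, 1 straw stands alone for its class and limma takes all spread from the 2 straws of the other class. Calls from those fits depend on which class keeps 2 straws and are not given. No limma call was therefore checked with 1 library left out.

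The other ways of pairing the libraries gave fewer genes by the same 2-fold rule. Oat and canola against triticale and flax gave 39 genes in total, and oat and flax against triticale and canola gave 7, compared with 240 for cereal against dicot. Limma called 0 genes in both of those splits, with 206 and 43 genes at an unadjusted p under 0.05. In 2 pairs that share no library, the log2 ratios of oat over canola and of triticale over flax had a Spearman's rho of 0.462 across genes. The other pairing of cereal over dicot straws, oat over flax with triticale over canola, gave a lower value of 0.293. Oat over triticale with canola over flax, which compares straws within a class, gave 0.182. The ratios were not corrected for each library's trend with gene length or expression level, and what these trends add to the coefficients was not tested.

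**Figure D2:**
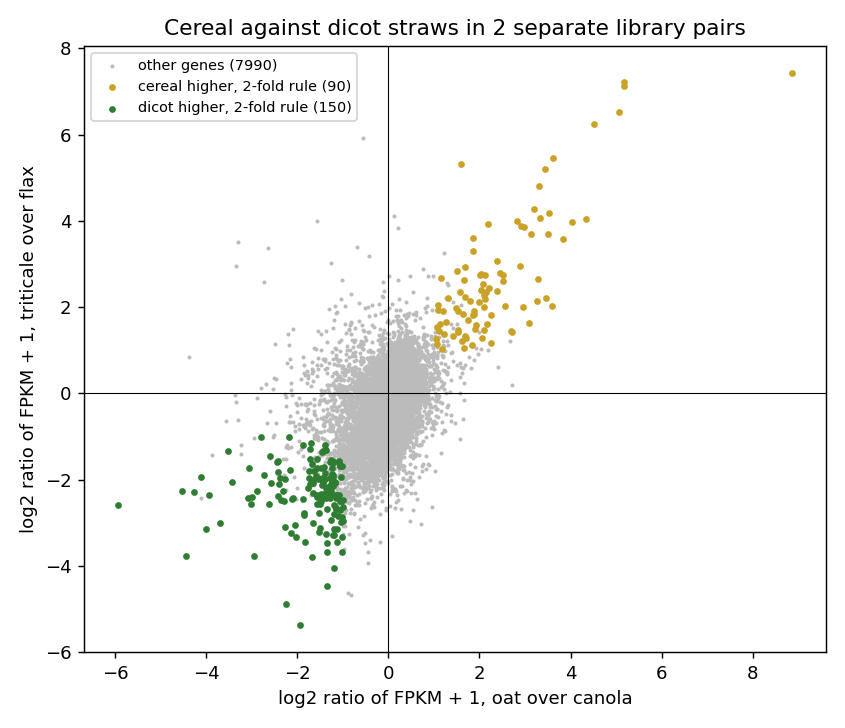
Log2 ratio of FPKM + 1 of oat over canola (horizontal axis) against that of triticale over flax (vertical axis), with 1 point per gene (8230 genes). The 90 cereal-higher genes lie in the upper right and the 150 dicot-higher genes in the lower left, and Spearman's rho across genes was 0.462.

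The second comparison, between the 2 cereal straws, was strongly one-sided. On oat 1169 genes were at least 2-fold above triticale, and on triticale 29 genes were at least 2-fold above oat. Few of these differences were large, since 5 and 1 genes passed 4-fold. On the scale of FPKM + 1 the widest were MYCTH_76393 (38.01 FPKM on oat, 6.67 on triticale, an FPKM ratio of 5.70) and MYCTH_2298417 (65.80 against 13.04, an FPKM ratio of 5.05). In the other direction they were MYCTH_106502 (19.1 FPKM on triticale, 3.79 on oat) and MYCTH_2133773 (23.3 against 5.59). These 2 genes were higher still on canola, at 45.9 and 39.8 FPKM, and lowest on flax, at 0.774 and 1.36 FPKM. Among the genes with a symbol, the ratio of oat to triticale was 3.27 for cat1 (95% counting interval 2.54 to 4.24), 2.87 for phy1 (1.51 to 5.83), 1.82 for gla1 (1.59 to 2.08), 1.62 for cbdA (1.58 to 1.66) and 1.09 for ganA (0.998 to 1.18). The ganA difference lies within counting error and turned sign under median centring. After median centring, 725 genes were higher on oat and 62 on triticale, and after removal of the trend with gene length 475 and 59. With the trend with expression level removed the counts were 386 and 151, and with both trends removed 350 and 126. With a pseudocount of 10 the counts were 117 and 4.

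The third comparison, between the 2 dicot straws, also compares 30 h on canola with 24 h on flax. On canola 651 genes were at least 2-fold above flax, 144 of them at least 4-fold, and on flax 286 genes were at least 2-fold above canola, 27 of them at least 4-fold. With a pseudocount of 10 the counts were 292 and 111. MYCTH_2309660 had 318 FPKM on canola and 5.07 on flax, a ratio of 62.7, and MYCTH_2314555 had 278 and 4.50, a ratio of 61.7. Both were also far above flax on the cereal straws, at 216 and 93.6 FPKM on oat and 365 and 86.6 FPKM on triticale. MYCTH_82772 had 738 FPKM on flax and 78.5 on canola, and MYCTH_2303328 had 4252 and 460. The ratio of flax to canola was 5.29 for cat1 (95% counting interval 4.84 to 5.79) and 1.36 for phy1 (1.05 to 1.75). The ratio of canola to flax was 3.68 for gla1 (3.31 to 4.11), 3.01 for ganA (2.78 to 3.26) and 2.24 for cbdA (2.15 to 2.34).

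The fourth comparison set each straw against the other 3. Canola had 240 genes at least 2-fold above every other straw and 18 below, flax had 123 above and 152 below, oat had 24 above and 4 below, and triticale had 2 above and 828 below. Without the canola library, with 1 straw fewer to clear, the counts above and below were 369 and 279 for flax, 88 and 8 for oat, and 11 and 883 for triticale. With a pseudocount of 10 they were 116 and 5 for canola, 64 and 60 for flax, 9 and 0 for oat, and 1 and 60 for triticale. The 240 canola-higher genes took 6.27% of canola reads, against 1.32% to 1.54% on the other straws. They included gla1, at 2.27 times the next straw, and the widest were MYCTH_64095 (211 FPKM on canola and 10.7 on flax, the next straw) and MYCTH_110028 (1219 FPKM on canola and 77.6 on triticale). The 123 flax-higher genes took 4.94% of flax reads, against 1.05% to 1.43% on the other straws. They included cat1, at 5.29 times the next straw, and the widest were MYCTH_82772 (738 FPKM) and MYCTH_69746 (659 FPKM on flax and 79.4 on canola). The widest among the genes lower on flax were MYCTH_2309660 and MYCTH_2314555, described for the dicot straws. On oat, MYCTH_2299856 reached 154 FPKM and MYCTH_2113877 19.3, against 40.2 and 4.82 on triticale, the next straw. Among genes with at least 10 FPKM on the other straws, MYCTH_2295414 and MYCTH_2309573 were the widest lower on oat, at 19.0 and 5.50 FPKM. The next lowest straw was 1.80 and 1.87 times as high, so neither is among the 4 genes below at 2-fold. The genes above on triticale were MYCTH_89872 (684 FPKM, with 332 on oat) and MYCTH_107763 (95.1, with 46.9 on canola). The widest among the genes lower on canola were MYCTH_37844 (9.57 FPKM, with 40.7 on flax) and MYCTH_2298752 (11.8, with 37.4 on oat).

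**Figure D3:**
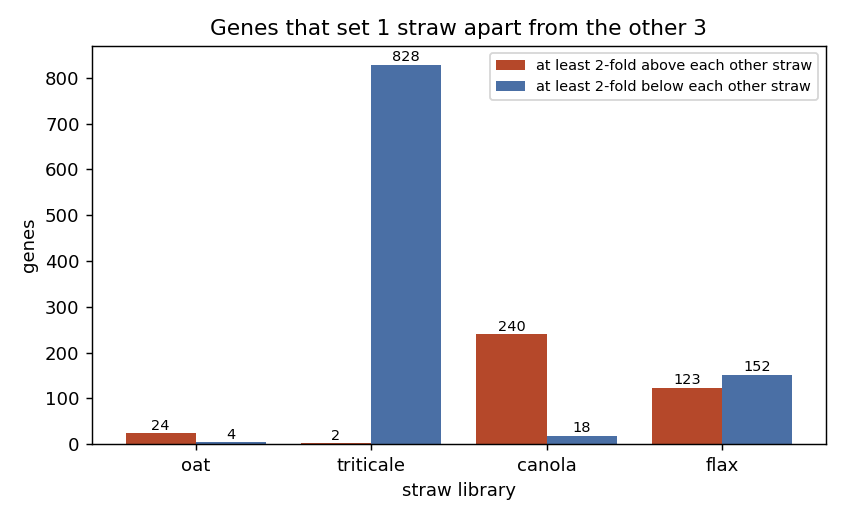
Number of genes (vertical axis) at least 2-fold above or below each of the other 3 straws, for each straw library (horizontal axis), with 1 library per straw and therefore no error bars. Canola has the most genes above (240) and triticale the most below (828).

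The 828 genes lower on triticale were mostly of moderate level, with a median of 17.6 FPKM over the other straws and 5.06 on triticale. MYCTH_2298417 and MYCTH_2313963 (1.97 FPKM on triticale, 10.6 on oat) were the widest, and cat1 and phy1 were among the 828. Their median length was 2071 bases, against 1797 for all tested genes. The triticale library differed from the others with gene length: its median log2 difference from the mean of the other straws was 0.14 in the shortest 20% of genes and -0.44 in the longest 20%. The same medians went from -0.01 to 0.14 on oat, from -0.09 to 0.13 on canola and from 0.01 to 0.16 on flax, where each includes triticale among the others. The triticale library also differed with expression level: the median was -0.41 in the 20% of genes with the lowest mean FPKM, -0.56 in the next 20% and 0.21 in the highest 20%. From the lowest to the highest 20% the medians went from 0.08 to -0.01 on oat, from 0.19 to -0.11 on canola and from 0.21 to -0.06 on flax. Of the genes in the second bin by level 17.8% were among the 828, against 2.49% in the highest. With the length trend removed, 293 genes were lower on triticale, 286 of them from the 828. With the level trend removed the count was 243, with 231 of the 828, and with both removed it was 220, with 209 of the 828. The genes above on triticale then numbered 8, 42 and 34, in the same order. After median centring the count was 491, and with a pseudocount of 10 it was 60.

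**Figure D4:**
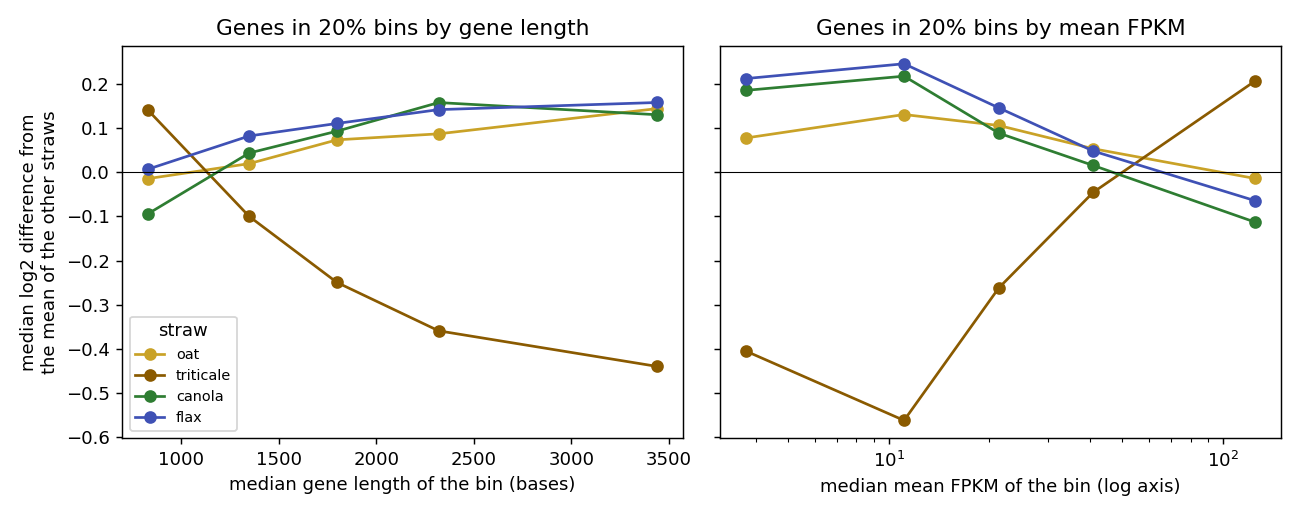
Median log2 difference of each straw library from the mean of the other 3 (vertical axis) in 5 bins of the 8230 genes, 1 line per straw, against the median length of the bin in bases (left panel, bins by length) or the median of mean FPKM (right panel, log axis, bins by mean FPKM). The triticale line falls from 0.14 in the bin of the shortest genes to -0.44 in that of the longest, and by level it lies at -0.56 in the second bin and 0.21 in the highest.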

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

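The settings were fixed before the data were examined, except the removal of trends with gene length and expression level and limma-voom on recovered reads, which were chosen after seeing the data. No paired analysis was possible because each straw has 1 library. The 29 gene lists gave no value under any setting. Depth limits genes near 0 reads, such as lcc1, and culture time limits every canola statement. With no filter on low values the fold counts kept within 1.5 times of the reported ones, while limma called 0 and 0 genes (cereal-higher, then dicot-higher); its fit then includes genes with no spread between straws, and 348 and 501 genes had an unadjusted p under 0.05. Limma without the trend called 16 and 1, limma-voom 33 and 7, median centring gave 87 and 135, upper-quartile scaling 70 and 50, removal of the length trend 109 and 161, of the level trend 62 and 24, and of both 47 and 11. All 45 and 10 genes called on the deposited scale were among those called under median centring, upper-quartile scaling and removal of either trend, and 40 and 9 with both trends removed. Leaving out 1 library gave a limma range of 0 to 165 cereal-higher and 0 to 283 dicot-higher genes; the lone straw of a class is then assumed to vary like the other class. By the 2-fold rule the ranges were 118 to 279 and 166 to 1356; without oat, triticale alone stands for the cereals, so the 1356 hold all 828 genes lower on triticale by construction. Without canola the counts above and below the remaining straws were 88 and 8 for oat, 11 and 883 for triticale, and 369 and 279 for flax.

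At 4-fold the class sets held 30 and 9 genes, oat against triticale 5 and 1, canola against flax 144 and 27. The genes above and below the other straws at 4-fold were 0 and 0 for oat, 0 and 2 for triticale, 35 and 0 for canola, and 14 and 21 for flax. A pseudocount of 10, which shrinks low genes, gave class sets of 58 and 34, oat against triticale 117 and 4, and canola against flax 292 and 111. Under it 9 and 0 genes were above and below for oat, 1 and 60 for triticale, 116 and 5 for canola, and 64 and 60 for flax. A pseudocount of 0.1 moved triticale over oat to 61 genes, oat to 37 above and 17 below, triticale to 4 above, and canola to 44 below. With a mean FPKM of at least 10, triticale over oat fell to 9 genes, oat below to 0 and canola below to 10. Median centring gave 725 genes for oat over triticale, 62 for triticale over oat, and 7 above and 491 below for triticale, and upper-quartile scaling gave 28 below for canola. Removal of the length trend gave 475 and 59 genes for oat against triticale, 8 above and 293 below for triticale, and 7 below for oat. Removal of the level trend gave 386 and 151 for oat against triticale, 42 above and 243 below for triticale, 7 below for oat and 28 below for canola. Removal of both gave 350 and 126, 34 above and 220 below for triticale, and 7 below for oat. The oat to triticale difference of ganA turned to -0.071 on the log2 scale under median centring. The causes of these changes were not tested except where the setting itself shows them.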

Other observations

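Genes that set flax or canola apart often lay side by side. In RefSeq gene order, 7 consecutive genes from MYCTH_2064854 to MYCTH_108314 were all at least 2-fold higher on flax than on every other straw, with a median of 164 FPKM on flax (89.5 to 1007) against 28.2 on oat, 25.8 on triticale and 40.8 on canola. They include MYCTH_69746 and MYCTH_82772, the widest of the flax-higher genes. A second group of 5 neighbours, MYCTH_2140533 to MYCTH_2316248, had a median of 57.5 FPKM on flax against 7.32 on oat, 8.09 on triticale and 17.4 on canola. On canola, 5 neighbours from MYCTH_78019 to MYCTH_114666 had a median of 28.1 FPKM, against 11.6 on triticale, 3.37 on oat and 1.09 on flax. They include MYCTH_106502, which was also higher on triticale than on oat. A group of 4 neighbours from MYCTH_94532 to MYCTH_2307822 was higher on both cereal straws, with medians of 45.8 FPKM on oat and 42.96 on triticale against 9.35 on canola and 4.57 on flax.

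The tests of chance placement for the neighbours, of scaling and of the splits of the libraries were chosen after the result was seen. Median centring was fixed beforehand as a setting, and only its use as a test of the triticale count came afterwards. The tests of overlap, depth, gene length and expression level were set before their own result was seen.

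Among the 122 flax-higher genes with a place in the gene order, 28 adjacent pairs were both called. In 1000 shuffles within 10 bins of expression level the mean was 1.65 pairs and the highest 7 (one-sided permutation p = 0.001, the smallest these shuffles can give; adjusted p = 0.001 over 5 sets). For canola there were 35 pairs against a highest of 18. Pairs whose RefSeq spans do not overlap numbered 28 and 34, which argues against reads counted for overlapping neighbours as the cause of the pattern. Why such neighbours were high together stays open: read sharing between related neighbouring copies was not tested, and the canola culture was grown for 30 h. The counts were 8 pairs against a highest of 5 for the cereal-higher set, 15 against 8 for the dicot-higher set and 112 against 101 for the triticale-lower set, each with the same p of 0.001.

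The 828 genes lower on triticale are a pattern in a single library. Fewer reads cannot account for it, since with every library thinned to the triticale total the count was again 828, with 793 genes shared, and scaling is not the whole cause, since 491 genes remained after median centring while the highest count for another library was 166. With the length trend removed the count was 293 against a highest of 176 for another library (difference 117, 95% interval 74.6 to 159.4). Removal of the length trend alone therefore left more lower genes on triticale than on any other straw. With the level trend removed the count was 243 against 187 (difference 56, 95% interval 15.4 to 96.6). These intervals take genes as independent, while the genes lower on triticale lay side by side more often than in any shuffle. The intervals may thus be too narrow, and whether the level trend alone accounts for the excess stays open. With both trends removed the counts were 220 on triticale and 182 on flax, a difference of 38 (95% interval -1.3 to 77.3, with genes taken as independent). Oat had 7 and canola 27 lower genes in the same setting. The flax count is itself that of 1 library without a replicate, so this comparison cannot tell whether an excess on triticale is left. The trends together may account for most of the 828. Such trends can come with a response to triticale straw itself or with the state or handling of RNA from that culture, which cannot be told apart with 1 library of triticale straw.

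For the class comparison, 1 of the 3 ways of splitting the 4 libraries into pairs, the cereal against dicot split itself, gave as many as 240 genes, and the highest of the others was 39. So few splits cannot give a share under 0.05.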
